A study of Homo sapiens with 3 samples.

How the data were processed

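Total RNA from 3 samples of H1975 cells transfected with siNC, siHHLA3-1 or siHHLA3-3 was sequenced. Per the labels' protocols, RNA was extracted with Trizol and treated with DNase I, and 1 ug of total RNA per sample went into Illumina libraries. Each group held 1 library. The differently numbered HHLA3 siRNAs are not called replicates in the labels, so each was its own group. The siRNA sequences were not given in the sources used here.

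The authors deposited 1 table of 16662 genes with 4 values per library. The deposited counts are whole numbers of reads per gene and are not normalised. The deposited CPM are those counts scaled to a common library total, per the file headers and the values. The deposited FPKM and TPM are the authors' values scaled by gene length and library. The smallest sum of FPKM over the libraries was 1.00, so genes below such a sum were left out of the table. Of the identifiers, 16509 are Ensembl genes and 153 are loci assembled from the reads, and 16482 were found in the gene name table. The build hg19 and the tools HISAT2, HISAT, TopHat2 and Bowtie2 are named in the submitters' processing notes, without versions. The program that counted reads, the annotation and the use of strand were not given in the sources used here, so genes that share reads with copies or with a gene on the opposite strand are uncertain.

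Library totals, recovered from the authors' counts and CPM, were 32813003 for siNC, 35069930 for siHHLA3-1 and 26950852 for siHHLA3-3. The unlisted share was 0.305%, 0.355% and 0.325%. Mitochondrially encoded genes took 6.25%, 6.24% and 5.95% of the total, and the 10 most abundant genes 6.85%, 6.56% and 6.35%. A count of 3, taken as the floor, corresponds to 0.0935, 0.0845 and 0.110 CPM. Intervals for a level are exact 95% Poisson intervals and those for a ratio are exact 95% binomial intervals, and both cover counting error only.

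Counts were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3 (0.978, 1.01 and 1.01) to normalised CPM. Ratios were taken as log2 of (CPM + 1) over (CPM + 1), which understates the differences of low genes. Folds printed as such are ratios of CPM without the added 1. Genes with a mean of at least 1 CPM over the libraries were kept, 13879 in all, and a gene was counted when its ratio reached 2-fold. With 1 library per group no p-value was computed for these counts. All gene lists, the rule for named genes, the filter, the threshold and most alternative settings were fixed before the data were examined. The other calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

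For each of 42 lists of pathway, lineage and other cell type genes, the median log2 ratio was set against 10000 random lists of the same size matched on deciles of mean expression. Lists with fewer than 5 members measured are given as values. The overlap of the siRNAs was set against the product of the list sizes over the number of genes, and against 100 simulations of unchanged libraries sharing 1 control. These drew counts with counting error alone or with the spread between the siHHLA3 libraries.

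The genes named in the text are HHLA3 and its listed neighbours; up to 12 higher and 12 lower genes with both siRNAs; up to 5 in each direction for each comparison; and up to 4 members of each list described, by size of the mean ratio. The first groups needed a mean of at least 5 CPM, and genes without a usual symbol were counted but not named. Some genes that the rule names are not reported here. The copies XAGE1A, GOLGA8B, MTX1 and U2AF1, and the gene LPAR6, were added after their values were seen where they fall outside this rule.

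The analysis was repeated with DESeq2 1.42.0 size factors, library totals alone, a pseudocount of 0.1, no filter, a mean of at least 5 CPM, the deposited TPM or FPKM, a 1.5-fold threshold, a counting interval in addition to size, and random lists without matching. The siHHLA3 libraries were also taken as 2 samples against 1, with edgeR's quasi-likelihood test and DESeq2 and a Benjamini-Hochberg adjusted p under 0.05. That fit has 1 residual degree of freedom, and the lone siNC library is assumed to vary like the others. Added after the data were seen were removal of a trend on gene length and GC content, thinning to the smallest library, and leaving out genes that carry the leading 7-mer of either siRNA. Length was known for 100% and GC content for 98.8% of genes.

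All 7-mers were scanned in the 3' UTRs annotated in GENCODE release 29 for genes of at least 5 CPM. For each of 16324 7-mers found in at least 30 of 10489 genes, a t statistic compared the ratios of genes with and without it, beside 100 permutations within deciles of UTR length. A gene without an annotated 3' UTR was not searched.

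The methods were tested on simulated data. For 13872 genes simulated with counting error alone, the 2-fold rule with both siRNAs recovered 100% of 50 genes raised and 92% of 50 genes lowered by 1.5 on the log2 scale, and called 0 unchanged genes. The fit of 2 libraries against 1, on 13862 simulated genes, called 14% of genes raised and 24% of genes lowered by 1 on the log2 scale, 98% and 94% at 2, and 7 unchanged genes. A 7-mer planted with a shift of -0.3 on the log2 scale in shuffled siHHLA3-3 ratios of 10489 genes took rank 1. Smaller shifts were not planted.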

Results

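RNA sequencing was carried out on H1975 cells, an established EGFR-mutant human lung adenocarcinoma line, after transfection with small interfering RNAs (siRNAs). There was 1 library with the control siRNA (siNC), 1 with siHHLA3-1 and 1 with siHHLA3-3, which are differently numbered siRNAs against HHLA3. Cells were transfected at about 70% confluency, kept 6 h without serum and harvested after a further 24 h in medium with 10% serum. The library totals were 32813003 reads for siNC, 35069930 for siHHLA3-1 and 26950852 for siHHLA3-3, over 16662 listed genes. There were no replicates, and the labels give each library its own batch, so batch and siRNA cannot be told apart. All differences below therefore describe these 3 libraries, and all intervals cover counting error only.

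The targeted gene was examined first. HHLA3, a gene named for its association with a long terminal repeat of the endogenous retrovirus HERV-H, was lower in both knockdown libraries. Its level was 5.99 CPM (normalised read counts scaled to a common library total) with siNC (192 counts, 95% interval 5.17 to 6.89). It was 1.55 CPM with siHHLA3-1 (55 counts, 1.17 to 2.02) and 0.735 CPM with siHHLA3-3 (20 counts, 0.449 to 1.13). HHLA3 was thus 3.86-fold lower with siHHLA3-1 (95% counting interval 2.85 to 5.31) and 8.15-fold lower with siHHLA3-3 (5.13 to 13.6). On the log2(CPM + 1) scale used throughout, the ratios to siNC were -1.45 and -2.01.

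**Figure D1:**
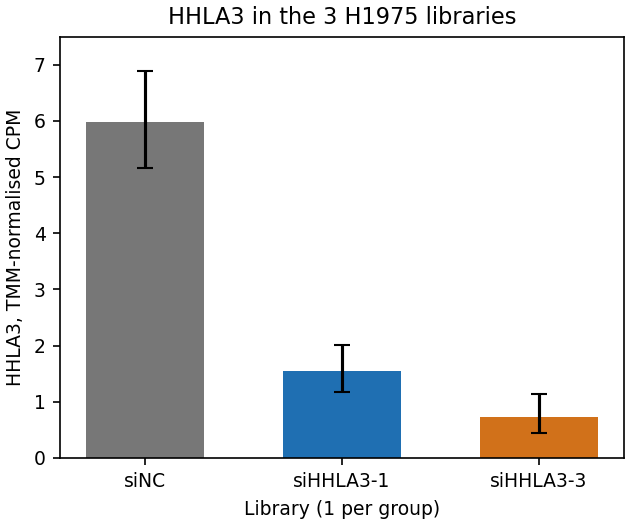
HHLA3 level in TMM-normalised CPM (vertical axis) in the siNC, siHHLA3-1 and siHHLA3-3 libraries, 1 library per bar, with exact 95% counting intervals as error bars. The siNC bar stands at 5.99 CPM and the knockdown bars at 1.55 and 0.735 CPM, with intervals that do not reach that of siNC.

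In GENCODE release 29 on GRCh38, which is not the build named in the submitters' processing notes, HHLA3 (ENSG00000197568) lies on chromosome 1 from 70354805 to 70385339 on the plus strand and is annotated there as protein coding. ANKRD13C lies on the opposite strand, with its nearest base 70 bp away at 70354734, and CTH begins 25878 bp downstream, at 70411218. ANKRD13C had log2 ratios of -0.29 with siHHLA3-1 and -0.11 with siHHLA3-3. CTH, which encodes the cystathionine gamma-lyase of cysteine synthesis, was 1.20-fold higher with siHHLA3-1 (1.01 to 1.42) and 2.40-fold higher with siHHLA3-3 (2.05 to 2.81). The ratios of the other measured neighbours were -0.19 and -0.24 for LRRC40, 0.08 and 0.00 for SRSF11, and 0.06 and 0.15 for ZRANB2.

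The comparison of both siRNAs with siNC asks which genes differ whichever siRNA was used against HHLA3. By list median, interferon-stimulated genes, NF-kB cytokines and immediate early genes were higher in both knockdown libraries, and mitotic and NRF2 target genes were lower. ATF4 targets were higher too, mainly with siHHLA3-3. In all, 17 genes were at least 2-fold higher and 8 at least 2-fold lower with both siRNAs, of 13879 genes above the expression filter. HHLA3 itself was among the 8 lower genes. The deposited TPM gave 108 higher and 49 lower, and a pseudocount of 0.1 gave 36 and 14. A gene list was taken to stand apart when its median log2 ratio lay outside the central 95% of 10000 expression-matched random lists with both siRNAs in the same direction. Of 38 lists with at least 5 measured members, 5 stood apart as higher and 4 as lower. Random lists do not move together as co-regulated genes do, so the percentiles describe these libraries and are not a test. In 20 simulations of unchanged libraries with the spread between the siHHLA3 libraries, 0.35 lists stood apart on average and at most 2. Those simulations also drew each gene independently, so they share this limit. Of the 9 observed calls, 3 ended under an alternative: those of the nuclear oxidative phosphorylation, WNT and solute carrier lists.

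The interferon response list had median log2 ratios of 0.56 with siHHLA3-1 and 0.27 with siHHLA3-3, and 37 of its 38 measured members were above 0 with each. RSAD2, the antiviral enzyme viperin, was 2.58-fold higher with siHHLA3-1 (72.4 to 187 CPM) and 2.90-fold higher with siHHLA3-3 (210 CPM). SAMD9L, IFIT2 and SAMD9 had log2 ratios of 1.74, 1.26 and 0.86 with siHHLA3-1 and 0.62, 0.61 and 0.97 with siHHLA3-3. The 17 measured NF-kB inflammatory genes had medians of 0.35 and 0.53. Among them the cytokine IL6 stood at 7.86 CPM with siNC, 12.5 with siHHLA3-1 and 26.4 with siHHLA3-3, and the feedback inhibitor TNFAIP3 at 49.3, 84.7 and 90.5 CPM.

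Genes of the ATF4 and amino acid response had medians of 0.16 with siHHLA3-1 and 0.62 with siHHLA3-3 over 32 measured members. Above 0 were 20 members with siHHLA3-1 and 28 with siHHLA3-3. Of the 32 members, 1 was at least 2-fold higher with siHHLA3-1 and 9 with siHHLA3-3. The stress-induced transcription factor DDIT3 (CHOP) had ratios of 0.52 and 1.89 and PPP1R15A of 0.61 and 1.53. The 15 measured immediate early genes had medians of 0.31 and 0.30, with ATF3 at 0.71 and 1.24 and EGR1 at 0.17 and 0.88. The 6 measured solute carriers for amino acids and glucose had medians of 0.38 and 0.33. That call ended without the genes carrying either of the 7-base sequences given below for the single siRNAs. The medians of the remaining members were 0.43 and 0.27.

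Genes of G2/M and mitosis had medians of -0.69 with siHHLA3-1 and -0.23 with siHHLA3-3. All 40 measured members were below 0 with siHHLA3-1 and 35 with siHHLA3-3, though 1 was 2-fold lower with siHHLA3-1 and 0 with siHHLA3-3. The anaphase activator CDC20 stood at 267, 134 and 182 CPM with siNC, siHHLA3-1 and siHHLA3-3, the spindle assembly factor TPX2 at 474, 264 and 295 CPM, and the kinesin KIF20A at 161, 83.4 and 102 CPM. NRF2 and glutathione genes had medians of -0.30 and -0.26 over 21 members, with GSR, glutathione reductase, at -0.64 and -0.91. The medians were -0.15 and -0.17 for 39 nuclear oxidative phosphorylation genes, and -0.33 and -0.34 for 9 WNT and stem-like genes, among them SOX2 at -0.50 and -1.06. The oxidative phosphorylation call held under 6 of 11 alternatives, and the WNT call ended without the genes carrying either 7-base sequence, its median of the mean ratio going from -0.34 to -0.18.

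**Figure D2:**
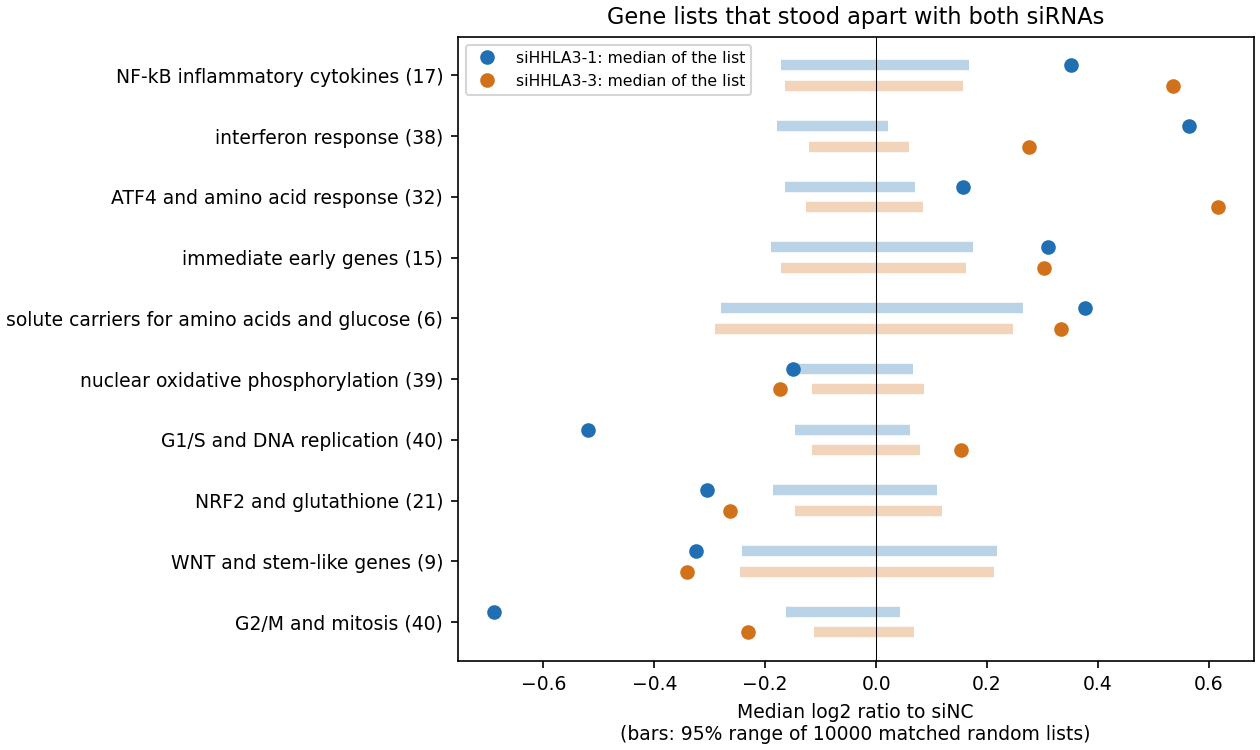
Median log2 ratio to siNC (horizontal axis, points) of the gene lists that lay outside the random range with both siRNAs, with the number of measured members in brackets; shaded bars span the 95% range of 10000 matched random lists. Interferon genes sit at 0.56 and 0.27, mitotic genes at -0.69 and -0.23, and the G1/S list on opposite sides of 0, at -0.52 and 0.15.

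Among the single genes higher with both siRNAs, the zinc finger gene ZNF554 was 2.80-fold and 3.28-fold higher with siHHLA3-1 and siHHLA3-3, and the histone deacetylase HDAC9 2.36-fold and 2.42-fold. BATF2, a transcription factor of the interferon response, was 2.54-fold and 2.12-fold higher. The histone demethylase KDM6B was 2.25-fold and 2.04-fold higher. ARID3A, ZNF702P, GOLGA8A, ZNF616 and DTX3 were also at least 2-fold higher with both, with ratios between 1.06 and 1.28. GOLGA8A shares sequence with GOLGA8B and its value is uncertain; GOLGA8B was itself higher by 16.7 and 12.9 CPM.

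The gene furthest below siNC was BOLA2B, at 31.9 CPM with siNC and 1.61 and 1.62 CPM with siHHLA3-1 and siHHLA3-3, or 19.9-fold and 19.8-fold lower. XAGE1B, a cancer-testis antigen, stood at 56.0 CPM with siNC and 8.39 CPM with siHHLA3-1, and was 15.6-fold lower with siHHLA3-3 (98 counts). Both belong to near-identical copies among which reads may be divided differently between libraries, so their values are uncertain, as is that of the pseudogene MTX1P1, with ratios of -1.17 and -1.51. MTX1P1 changed by -9.87 and -11.5 CPM and its listed copy MTX1 by -1.30 and -2.28 CPM. The kinase HIPK2, a regulator of p53, went from 386 CPM to 188 and 143 CPM, or 2.06-fold and 2.70-fold lower. Its 3' untranslated region (UTR) carries both of these 7-base sequences, and that of STRADB carries CAGAATG. STRADB had ratios of -1.22 and -1.47, and PADI4, a peptidylarginine deiminase, -1.01 and -1.27.

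Comparisons against the same siNC library share its chance values. Independent lists would share 1.09 higher and 0.783 lower genes. Unchanged libraries simulated with the spread between the siHHLA3 libraries shared 16.2 higher genes (range 5 to 26) and 7.26 lower genes (2 to 16), and with counting error alone 0 and 0. The number of shared genes was therefore within what the first simulation gave without any effect, although that spread also holds siRNA-specific differences. Across genes, which are not independent replicates, the ratios of the siRNAs had a Pearson correlation of 0.352 and a Spearman correlation of 0.367. Simulated unchanged libraries gave higher values, 0.499 and 0.481 with that spread and 0.491 and 0.449 with counting error alone. A shared control alone gives such values, and siRNA-specific differences can lower them. The observed correlation is therefore no evidence for or against a shared effect. The covariance of the ratios was 0.0450, against 0.0811 simulated with that spread and 0.00449 with counting error alone. In covariance the simulation with that spread was thus wider than these data. It gave only 197 genes 2-fold apart between the siRNAs, however, where 399 were observed. Its numbers of shared genes may therefore be too high or too low. The siNC data are 1 library and could not be split, so part of the shared difference may come from it.

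**Figure D3:**
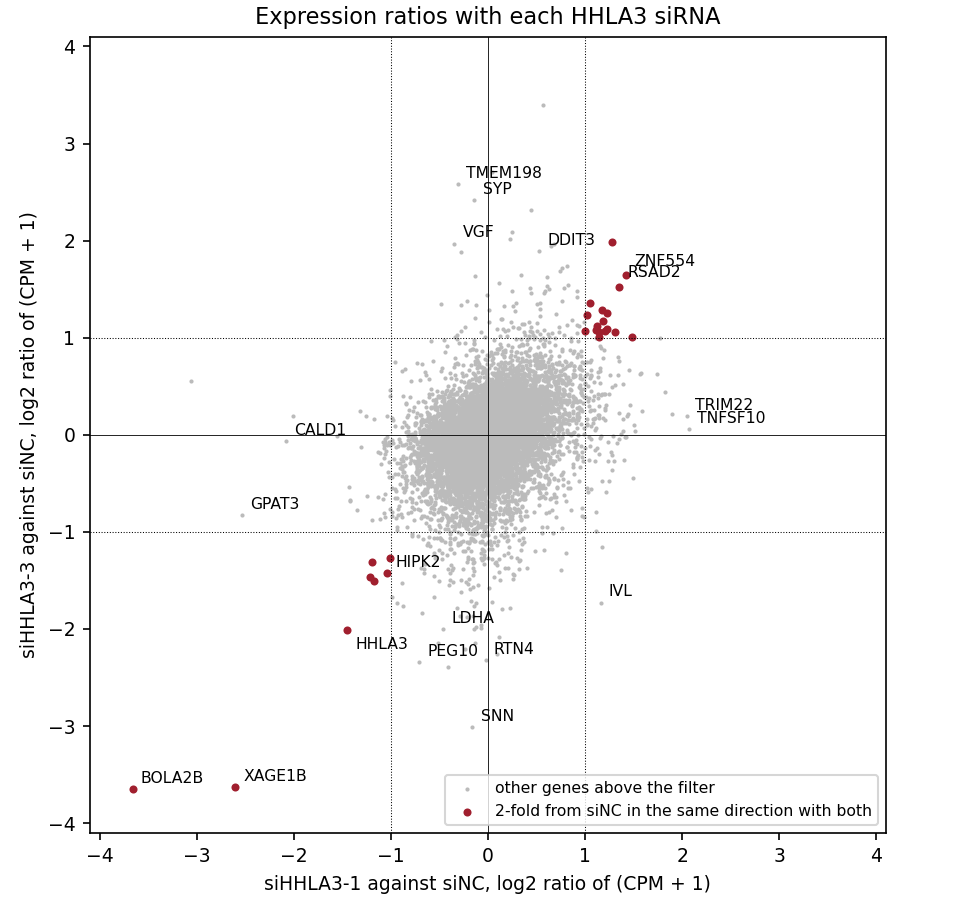
Log2 ratio of (CPM + 1) to siNC with siHHLA3-1 (horizontal axis) and siHHLA3-3 (vertical axis) for the 13879 genes above the filter, with dotted lines at 2-fold. Red points are the 25 genes at least 2-fold from siNC in the same direction with both siRNAs; BOLA2B and XAGE1B lie furthest below, and SNN and RTN4 lie below siNC with siHHLA3-3 while near 0 with siHHLA3-1.

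With siHHLA3-1, interferon and class I antigen presentation genes were higher than with siNC, and cell cycle, ribosome biogenesis and heat shock genes were lower. At least 2-fold differences were found in 188 genes, 135 higher and 53 lower. The deposited TPM gave 357 and 164, and a pseudocount of 0.1 gave 233 and 80. Unchanged libraries simulated with the spread between the siHHLA3 libraries gave 192 genes (range 154 to 225), which covers the 188. That spread also holds siRNA-specific differences. TNFSF10, the death ligand TRAIL, was 5.24-fold higher (4.22 to 6.57), at 15.9 against 3.02 CPM, and the antiviral TRIM22 was 4.37-fold higher (3.94 to 4.85). GPAT3, an acyltransferase of triglyceride synthesis, was 6.08-fold lower (5.58 to 6.63), and CALD1, the actin-binding caldesmon, 4.35-fold lower (4.05 to 4.68).

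All 15 antigen presentation genes were above 0 with siHHLA3-1, with a median of 0.52, against 0.10 with siHHLA3-3. Their transactivator NLRC5 stood at 168 CPM with siNC and 325 CPM with siHHLA3-1. Apoptosis regulators had a median of 0.28, with 20 of 23 above 0, or 0.16 without the genes carrying CAGAATG or GTGAACT, and the BH3-only genes BMF and HRK at 1.40 and 1.16. Medians above the random range were also found for immune checkpoint and surface ligand genes (0.43), mesenchymal genes (0.27), autophagy and lysosome genes (0.12, with the kinase ULK1 at 1.21) and matrix and invasion genes (0.09, or 0.05 without the genes carrying either sequence). Of the 14 measured mesenchymal genes 11 were above 0 and 3 below, among the latter SNAI2 at -0.89. DNA replication genes of G1/S had a median of -0.52, with 39 of 40 below 0. MYC and ribosome biogenesis genes had a median of -0.34, with 25 of 26 below 0, cytosolic ribosomal proteins -0.23, with 50 of 51 below 0, and heat shock proteins -0.41, with 15 of 15 below 0. For the ribosomal proteins the random range itself lay below 0, from -0.17 to -0.009. Their number below 0 therefore partly reflects an offset of equally abundant genes. The ornithine decarboxylase gene ODC1 stood at 109 CPM with siNC and 56.2 CPM with siHHLA3-1, and its 3' UTR carries CAGAATG. The chaperone HSPA8 stood at 1782 and 1116 CPM.

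ATG9B went from 37.7 to 136 CPM with siHHLA3-1, and IGFN1 was 3.64-fold higher. U2AF1L5 was 4.35-fold higher, but it is a near-identical copy of U2AF1 and its value is uncertain; U2AF1 itself was higher by 4.56 CPM, against 14.5 CPM for U2AF1L5. Reference housekeeping genes had a median of -0.22 with siHHLA3-1 and -0.08 with siHHLA3-3, both inside the random range. Of the 40 genes lower with siHHLA3-1 and not with siHHLA3-3 whose 3' UTR was searched, 25 carried the 7-base sequence CAGAATG there (62.5%). The share was 16.8% for all searched genes. CAGAATG was chosen as the sequence with the lowest t in the scan of these same ratios, so a high share is partly built in. GPAT3 carried CAGAATG and CALD1 did not. Among the 114 searched genes higher with siHHLA3-1, 16 carried it (14.0%), TRIM22 and IGFN1 included. Among the 12 searched genes higher with both siRNAs, 3 carried it, HDAC9 and GOLGA8A included.

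With siHHLA3-3, ATF4 targets and EGFR and MAPK output genes were higher than with siNC. Lower genes outnumbered higher ones on the main scale. That order was not kept with the deposited TPM (347 higher, 340 lower) or without the genes carrying either 7-base sequence (100 and 68). At least 2-fold differences were found in 317 genes, 112 higher and 205 lower. The simulation with the spread between the siHHLA3 libraries gave 194 genes (166 to 220) without any effect. Between the siHHLA3 libraries themselves, to which that spread was fitted, it gave 197 genes where 399 were observed. It thus understates large differences, so 317 above 194 does not show an effect. SYP, which encodes the synaptic vesicle protein synaptophysin, was 7.11-fold higher (5.59 to 9.16), at 17.3 against 2.43 CPM. VGF, a neuropeptide precursor, was 3.97-fold higher, at 204 against 51.4 CPM, and BSN, a presynaptic scaffold, 4.43-fold higher. SNN was 8.72-fold lower (7.72 to 9.88), and the reticulon RTN4 5.04-fold lower, at 84.4 against 426 CPM.

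TMEM198 was 8.69-fold higher (6.61 to 11.6) with siHHLA3-3, from 1.84 CPM with siNC. The antisense transcript HIF1A-AS3 was 4.73-fold higher, but without knowledge of strand in the counting its reads cannot be separated from those of an overlapping gene. The retrotransposon-derived PEG10 was among the more abundant lower genes, at 1379 CPM with siNC and 271 CPM with siHHLA3-3, or 5.09-fold lower. LDHA, lactate dehydrogenase A, stood at 2196 and 548 CPM, 4.01-fold lower, while the glycolysis list as a whole had a median of -0.05, which was above 0 with the deposited TPM. The sterol enzyme gene MSMO1 was 3.49-fold lower and HMGCS1 had a ratio of -0.92, in a cholesterol synthesis list with a median of -0.15 (18 of 24 below 0).

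EGFR and MAPK output genes had a median of 0.33 with siHHLA3-3, with FOSL1 at 1.07 and ETV5 at 0.88. YAP and TEAD targets had a median of 0.26, or 0.52 without the genes carrying either 7-base sequence, with the receptor tyrosine kinase AXL at 6.61 and 16.6 CPM. Hypoxia response genes had a median of 0.16. TGF-beta targets (-0.30) and epithelial junction and keratin genes (-0.19) had medians below the random range, and -0.27 and -0.19 without the genes carrying either 7-base sequence. The TGF-beta members ID2 (-0.64), TGFBR1 (-0.62) and TGFBR2 (-0.48) carry GTGAACT, and SMAD7 (0.71) does not. With siHHLA3-1 their ratios were -1.13, -0.45, -0.36 and 0.58, and none of them carries CAGAATG. Carriage alone therefore does not account for these values. Among the epithelial genes KRT19 was at -0.63, while CLDN1 and MUC1 were at 1.35 and 0.69. Of the 191 searched genes lower with siHHLA3-3 and not with siHHLA3-1, 122 carried the 7-base sequence GTGAACT in the 3' UTR (63.9%), against 11.4% of all searched genes. GTGAACT was likewise chosen from these same ratios. SNN, RTN4, PEG10, LDHA and MSMO1 all carried it. Without the genes carrying either 7-base sequence, 168 genes differed, 100 higher and 68 lower. With the deposited TPM the split was 347 higher and 340 lower, or 50.5% higher, against 35.3% on the main scale.

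The libraries with siHHLA3-3 and siHHLA3-1 were also compared directly, a difference that holds siRNA sequence, batch and library together. Cell cycle, ribosome biogenesis, ATF4 and EGFR output genes were higher with siHHLA3-3, and interferon, antigen presentation and apoptosis genes were lower. At least 2-fold differences were found in 399 genes, 105 higher and 294 lower. With the deposited TPM 36.3% of such genes were higher, against 26.3% on the main scale. The simulation with the spread between these libraries gave 197 genes (166 to 234). That spread was fitted to the difference between these same libraries. The lower number therefore shows that the simulation understates large differences, and it is no evidence of an effect. IVL, the epidermal protein involucrin, was 8.65-fold lower with siHHLA3-3 (7.28 to 10.4), at 5.18 against 44.8 CPM. ERG28, whose 3' UTR carries GTGAACT, was 5.42-fold lower and CDH5, VE-cadherin, 6.37-fold lower (5.06 to 8.11). NRARP, a feedback regulator of Notch signalling, was 4.78-fold higher, at 55.5 against 11.6 CPM.

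The list medians of siHHLA3-3 relative to siHHLA3-1 were 0.61 for G1/S genes, 0.44 for G2/M genes, 0.46 for MYC and ribosome biogenesis genes (26 of 26 above 0), 0.56 for ATF4 genes, 0.55 for EGFR and MAPK output genes, 0.25 for heat shock proteins and 0.18 for hypoxia genes. They were -0.23 for interferon genes (30 of 38 below 0), -0.37 for antigen presentation genes, -0.24 for apoptosis regulators, -0.30 for mesenchymal genes, -0.22 for epithelial genes, and -0.21 for both TGF-beta targets and cholesterol synthesis genes. Of 38 lists, 14 lay outside the random range in this comparison, against 19 for siHHLA3-1 and 16 for siHHLA3-3 relative to siNC.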

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

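Chosen after the results were seen were the tests on the 7-mers of siHHLA3-1 and siNC and the test of the siNC library's state. Thinning, trend removal and leaving out 7-mer genes were added after the data were seen, but before their own results were. The differences between the siRNAs in the next paragraph were not tested.

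Relative to siNC, 2 genes differed 2-fold in opposite directions. IVL stood at 19.5 CPM with siNC, 44.8 with siHHLA3-1 and 5.18 with siHHLA3-3, a log2 ratio of -2.89 between the siRNAs, and its 3' UTR carries GTGAACT. CDH5 stood at 7.95, 19.2 and 3.01 CPM, a ratio of -2.33. The list of G1/S and DNA replication genes was below siNC with siHHLA3-1 (median -0.52) and above it with siHHLA3-3 (0.15), with a median ratio of 0.61 between them. Of its 40 members, 39 were below 0 with siHHLA3-1 and 12 with siHHLA3-3.

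With siHHLA3-3, 197 genes were 2-fold lower that were not so with siHHLA3-1, and 45 were lower with siHHLA3-1 and not with siHHLA3-3. Thinning all libraries to the smallest total gave 190 in place of 197, which argues against the lower depth of the siHHLA3-3 library. In the scan of 7-mers the lowest t was -24.5 for GTGAACT with siHHLA3-3, against -5.28 in permutations, and -11.7 for CAGAATG with siHHLA3-1, against -4.72. Seed-like silencing of other transcripts by each siRNA may therefore account for part of these genes. Of the searched ones 63.9% and 62.5% carried the respective 7-mer. The 7-mers were chosen from these same ratios, so these shares are not separate support. Both 7-mers occur in HHLA3 transcripts (GTGAACT in 4 of 7, CAGAATG in 7 of 7), the siRNA sequences were not used here, and an effect of the different HHLA3 levels stays open as untested.

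Interferon genes were higher and mitotic genes lower with both siRNAs, as would also arise if the single siNC library were unusual. Silencing by the siNC oligonucleotide would raise genes with its seed match, but the highest t of any 7-mer for the mean of both siRNAs was 4.58, below the 4.94 of permutations. Without genes carrying either 7-mer the median of the mean ratio was -0.47 for mitotic genes, as before. This argues against silencing of those carriers as the whole cause of the mitotic shift. For interferon genes it was 0.53, 0.41 before, but silencing lowers its targets, so leaving them out could not shrink a rise. Indirect effects of silenced genes outside the lists were not tested. After removal of the length and GC trend the medians were -0.42 and 0.45, which argues against that trend as the whole cause. The state or batch of the siNC library cannot be told apart from an effect of the siRNAs, because it is 1 library with its own batch label. The covariance of the ratios differed from that simulated with the siHHLA3 spread by -0.0361. This cannot decide the question, since that spread also holds siRNA-specific differences. Lower HHLA3, and a response to these siRNA duplexes that siNC does not give, both stay open as untested.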

How the results depend on the processing

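The alternatives on trend removal, thinning and 7-mers were chosen after the data were seen. No paired analysis was possible because each group is 1 library. No named 2-fold difference and no list that stood apart changed direction, but the siHHLA3-3 split went from 112 higher and 205 lower to 100 and 68 without the 7-mer genes and to 347 and 340 with the deposited TPM. Of 3412 values of named genes under the alternatives, 3028 moved by less than their counting interval and 384 by more. Of 417 list medians, 385 stayed within the spread of random lists and 32 did not. The calls of the interferon, NF-kB, G2/M, ATF4, NRF2, immediate early and G1/S lists held under all 11 alternatives. That of nuclear oxidative phosphorylation held under 6, ending with the deposited TPM and FPKM, trend removal, thinning and without the 7-mer genes, and those of the WNT and solute carrier lists ended without the 7-mer genes. The cause of the following differences was not tested, except where fewer genes or a lower threshold explain them by construction. A pseudocount of 0.1 gave 313 genes for siHHLA3-1 (main 188), 50 for both siRNAs (25), and an HHLA3 ratio of -2.87 with siHHLA3-3 (-2.01). The deposited TPM gave 521 genes for siHHLA3-1, 687 for siHHLA3-3 (317), 779 between the siRNAs (399), 157 for both, and a correlation of 0.399 (0.352). The deposited FPKM gave 208 for siHHLA3-3, 237 between the siRNAs and a correlation of 0.379. A 1.5-fold threshold gave 1161, 1279, 1695 and 250 genes for siHHLA3-1, siHHLA3-3, between them and both. Without the 7-mer genes, 168 genes were counted for siHHLA3-3 and 227 between the siRNAs, with a correlation of 0.382. Taken as 2 libraries against 1, edgeR's quasi-likelihood test called 1 gene (BOLA2B, adjusted p 0.0498) with 349 at an unadjusted p under 0.05, and DESeq2 called 5 (RSAD2, ZNF554 and LPAR6 higher, BOLA2B and XAGE1B lower), with 231; LPAR6 was named after its values were seen. Neither test called HHLA3 itself, which was 3.86-fold lower with siHHLA3-1 and 8.15-fold lower with siHHLA3-3. HHLA3 had no value under the filter of 5 CPM, which its mean did not reach. The rescaling of FPKM was meant for a table without counts and was not run. Depth limits low genes such as HHLA3, with 20 counts in the siHHLA3-3 library.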

Other observations

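The tests on XAGE1B and BOLA2B were chosen after their values were seen, and the rest of this part gives values of lists fixed in advance. The checkpoint ligand CD274 (PD-L1) stood at 42.5 CPM with siNC, 58.0 with siHHLA3-1 and 119 with siHHLA3-3, and PDCD1LG2 (PD-L2) at 6.52, 16.4 and 7.35 CPM. The 16 genes of that list had medians of 0.43, above the random range, with siHHLA3-1 and -0.01 with siHHLA3-3; between the siRNAs the median was -0.14, inside that range. The lung lineage factor NKX2-1 stood at 65.7, 72.0 and 35.0 CPM, and its 3' UTR carries GTGAACT; the 8 lung lineage genes measured had medians of 0.04 and -0.17. CIITA, the class II transactivator, stood at 25.2, 26.9 and 10.9 CPM, and its 3' UTR carries both GTGAACT and CAGAATG. The p53 targets BBC3 (1.34 and 0.81) and SESN2 (0.76 and 1.38) were higher, while that list had medians of 0.05 and 0.08, or 0.02 and 0.21 without the genes carrying either 7-mer.

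The medians with siHHLA3-1 and siHHLA3-3 were -0.07 and -0.22 for replication-dependent histones, -0.10 and -0.14 for ER chaperones, 0.05 and -0.18 for metallothioneins, and -0.21 and -0.07 for ferroptosis genes. They were -0.13 and -0.10 for fatty acid synthesis, -0.14 and -0.05 for glycolysis, -0.06 and -0.15 for mitochondrially encoded genes, -0.08 and -0.11 for the Notch pathway, and -0.06 and 0.09 for microRNA machinery. The HHLA3 neighbours had medians of 0.06 and 0.00, and of the 2 other HHLA family genes sought, HHLA1 and HHLA2, 0 were listed. Medians that changed sign under another scaling or deposited unit were, with siHHLA3-1, those of hypoxia and mitochondrially encoded genes, and with siHHLA3-3, those of apoptosis, ferroptosis, glycolysis, matrix, autophagy and immune ligand genes. Under trend removal the siHHLA3-1 median of cholesterol synthesis changed sign, and under thinning those of lung lineage genes with siHHLA3-1 and of the neighbours with siHHLA3-3. Without the 7-mer genes, the Notch medians turned to 0.06 and 0.13 and the siHHLA3-3 median of ER chaperones to 0.03, with -0.20 for siHHLA3-1. The histone median with siHHLA3-1 and the apoptosis, ferroptosis, matrix, autophagy and immune ligand medians with siHHLA3-3 also changed sign. In the same setting the lung lineage medians were 0.13 and -0.09, and that of microRNA machinery with siHHLA3-1 was -0.10. Markers of other cell types had few measured members, 4 haematopoietic (0.13 and 0.08), 2 fibroblast (0.64 and -0.08) and 4 endothelial (0.27 and 0.02).

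XAGE1B and BOLA2B, the genes furthest below siNC with both siRNAs, have near-identical copies to which reads could be assigned differently between libraries. The listed copy XAGE1A changed by -0.671 CPM with siHHLA3-1 and by -0.187 CPM with siHHLA3-3 while XAGE1B changed by -47.7 and -52.5 CPM, which argues against a move of reads to that copy. BOLA2B was lower by 30.3 CPM with siHHLA3-1, and its copies were not analysed here, so a move of reads cannot be told apart from a lower level. Neither gene carries GTGAACT or CAGAATG in its annotated 3' UTR, and the equal BOLA2B levels of 1.61 and 1.62 CPM may as well reflect a high value in the single siNC library.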
